A study of Homo sapiens with 6 samples.

How the data were processed

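RNA-seq libraries of cells labelled MCF7 were compared in 2 groups of 3, shNC and shUSP27X, assigned from the sample titles. Per the labels' protocols, RNA integrity was checked on a Bioanalyzer and libraries were made with the NEBNext Ultra RNA kit. CASAVA is named in the submitters' processing notes; the aligner, the counting tool and its strand setting, and the genome build are not given in the sources used here. The deposited table holds whole-number read counts per gene, not normalised by the authors as far as the values show, with a gene length, position and biotype for each gene. The positions of all 58735 genes equal those of GENCODE release 29 (GRCh38), which was used for transcript sequences. The 6 count columns were matched to samples by title.

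Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (15007 kept), library sizes were scaled with TMM factors, and dispersions and the quasi-likelihood fit were robust, with the group as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold and a 2-fold change as the size limit. CPM values use TMM effective library sizes. Standard errors are the absolute log2 fold change over the square root of F, and 95% intervals use the total degrees of freedom. Total counts were 13408238 to 16121346 per library, and 3 counts, the limit that a count of 0 allows, equal 0.184 to 0.226 CPM. Intervals and limits of single counts cover counting error only, since reads without molecular identifiers are not independent molecules. The biological coefficient of variation was 13.4%. Within groups, counts of library pairs differed by more than sampling noise (chi-square per degree of freedom 3.85 to 28.3), so each library counted as 1 sample.

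Before the data were examined, 24 gene lists, the design, the alternatives and the rule for named genes were fixed. The lists cover ribosome biogenesis, immediate early genes, G1/S and DNA replication, cytosolic ribosomal proteins, mesenchymal and fibroblast markers, cholesterol synthesis, NF-kB inflammatory response, heat shock proteins, mitochondrially encoded genes, replication-dependent histones, ATF4 stress response, estrogen response, the unfolded protein response, p53 targets, interferon-stimulated genes, basal and luminal epithelial markers, G2/M and mitosis, reported USP27X substrates, the Polycomb group, the SAGA deubiquitinase module, the BCL2 family, hypoxia and glycolysis, and immune cell markers. The 23 lists with a tested member were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Of the 10 lists called with the preset, ribosome biogenesis, G1/S and DNA replication, and mesenchymal and fibroblast markers, 3 in all, were called with an estimated correlation. Named genes were USP27X; the 6 largest rises and 6 largest falls among protein-coding genes past the threshold, at 4 CPM or more and without overlap of the groups; up to 3 members of each list with the smallest adjusted p, or 1 where none passed; and USP22, USP51, SNAI1, CBX2, BCL2L11, CCNE1, HES1 and ESR1. This gave 85 genes.

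Shares of counts were compared by two-sided exact permutation tests. Alternatives were RLE factors, library size only, no filter beyond a total of 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, each library left out in turn, and protein-coding genes only. Leaving out shNC 1 and shUSP27X 2 together was added after seeing the data. The steps were tested on simulated counts for 15007 genes with 200 genes changed in this comparison. Changed genes were drawn from those with at least 60 counts in total over all libraries. Of 100 genes changed 2-fold, 76% were recovered, and of 100 changed 1.5-fold, 30%. Recovery at an adjusted threshold depends on the share of genes changed. That share was smaller here than the 2874 genes called in the data, so these rates do not give the power of the real comparison. Of 115 calls, 9 were unchanged genes, and 0 of 20 unchanged lists were called. Genes were simulated independently of each other, and unchanged lists were filled at random. The simulation therefore does not test false list calls where the members of a list are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.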

Results

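RNA was sequenced from cells labelled MCF7, a line described as estrogen receptor-positive luminal breast cancer cells, after introduction of a short hairpin RNA. The libraries fell into 2 groups of 3, labelled shNC (the control hairpin) and shUSP27X (a hairpin against USP27X, an X-linked deubiquitinase). The deposited values were read counts for 58735 genes. Total counts were 13927471, 16121346 and 13408238 in shNC 1, 2 and 3, and 14159287, 13452234 and 15382966 in shUSP27X 1, 2 and 3. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The single comparison asked how gene expression differed between the libraries labelled shUSP27X and the control libraries, with n = 3 per group.

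USP27X mRNA was measured first. USP27X (ENSG00000273820) lies on the plus strand of chromosome X at 49879948 to 49882565 (GRCh38), and its annotated transcript covers all 2618 bases without an intron. Its counts were 102, 105 and 83 in the control libraries and 81, 94 and 89 in those labelled shUSP27X. The normalised level was 6.63 ± 0.628 CPM (SD, n = 3) in shNC and 6.24 ± 0.740 CPM (SD, n = 3) in the libraries labelled shUSP27X. The log2 fold change was -0.09 (SE 0.16, 95% interval -0.46 to 0.28), with an edgeR adjusted p = 0.739. USP27X was therefore not detectably lower, and a 2-fold fall lay outside the interval. Because the target does not bear out the label, the group is called the libraries labelled shUSP27X throughout, and each direction below is that of the labels. The paralogs USP22 (log2 fold change 0.03, adjusted p = 0.808) and USP51 (log2 fold change 0.39, adjusted p = 0.440) did not pass the test either. USP51 ran from 0.15 to 0.65 when single libraries were left out and passed in none of the alternatives.

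**Figure D1:**
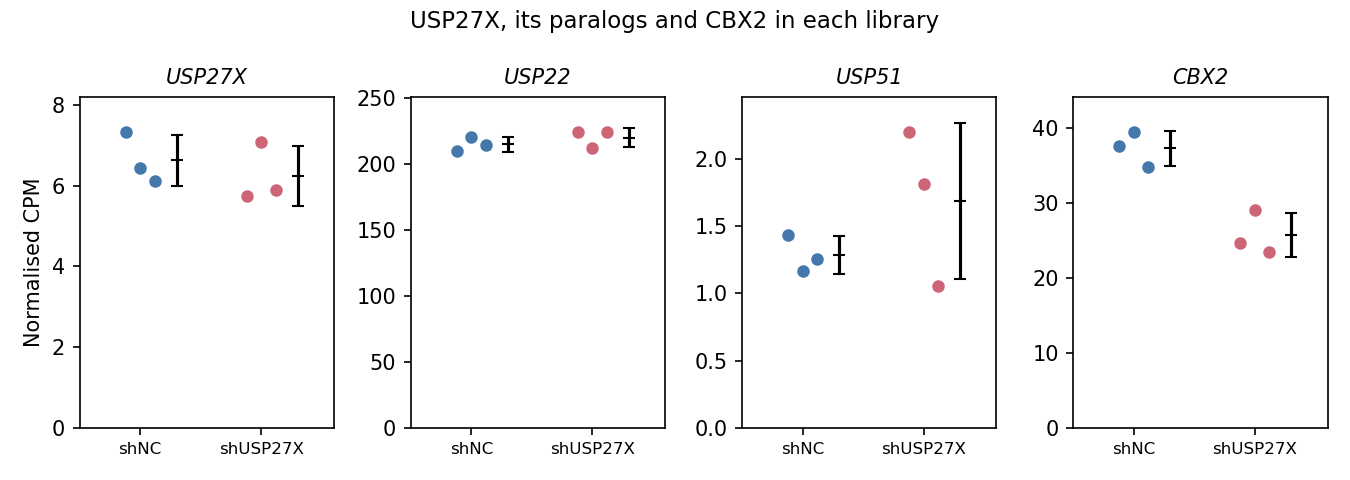
Normalised CPM (vertical axes, each starting at 0) of USP27X, USP22, USP51 and CBX2 in the 3 shNC libraries (blue) and the 3 libraries labelled shUSP27X (red); points are libraries, and bars give the mean ± SD. USP27X overlapped between the groups (6.63 and 6.24 CPM on average), while CBX2 averaged 37.2 CPM in shNC and 25.7 CPM in the libraries labelled shUSP27X.

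Several genes of the luminal, estrogen receptor-positive profile for which MCF7 is known were low in the 6 libraries, and others were not. ESR1, the estrogen receptor, was at 1.15 to 2.21 CPM, and the luminal transcription factor GATA3 at 0 to 0.431 CPM. The adhesion gene CDH1 was at 0.142 to 0.958 CPM, KRT19 at no more than 0.213 CPM and the progesterone receptor PGR at no more than 0.132 CPM. A count of 0 allows a level of up to 0.226 CPM in the library with the highest such limit (3 counts, counting error only). Over the 24 genes of a luminal identity list the median was 1.01 to 1.36 CPM per library, and 12 genes stayed under 1 CPM in all 6 libraries. KRT8 (340 to 663 CPM) and KRT18 (206 to 366 CPM), keratins of simple epithelia that belong to the same list, were abundant. Also of that list, TFAP2A was at 61.5 to 82.1 CPM, MUC1 at 20.9 to 33.1, TFAP2C at 17.1 to 24.2, ERBB3 at 11.9 to 14.1 and FOXA1 at 10.97 to 13.3 CPM. From the mesenchymal list VIM (292 to 411 CPM), and from the basal list EGFR (429 to 717 CPM) and CD44 (299 to 577 CPM), were abundant too. Other genes of those lists stayed under 1 CPM in all 6 libraries. They were 7 of 22 basal genes, among them KRT5 (0 CPM) and TP63 (at most 0.431 CPM). Of 30 mesenchymal and fibroblast genes they were 10, among them COL1A2 (0 CPM) and SPARC (at most 0.503 CPM). At 20 CPM or more in all 6 libraries were 14 basal, 11 mesenchymal and fibroblast, and 4 luminal genes. The median per library was 41.8 to 65.6 CPM for the basal list and 4.33 to 8.19 CPM for the mesenchymal and fibroblast list. KRT5, TP63, COL1A2, SPARC, TFAP2A, TFAP2C, ERBB3 and FOXA1 were chosen after their values were seen. MTAP, CDKN2A and CDKN2B, at a locus that MCF7 is known to lack, were at 75.7 to 96.2, 165 to 332 and 27.8 to 63.0 CPM. Of 21 immune cell markers none reached the count minimum for testing, and the highest value of any was 1.36 CPM (CD19).

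**Figure D2:**
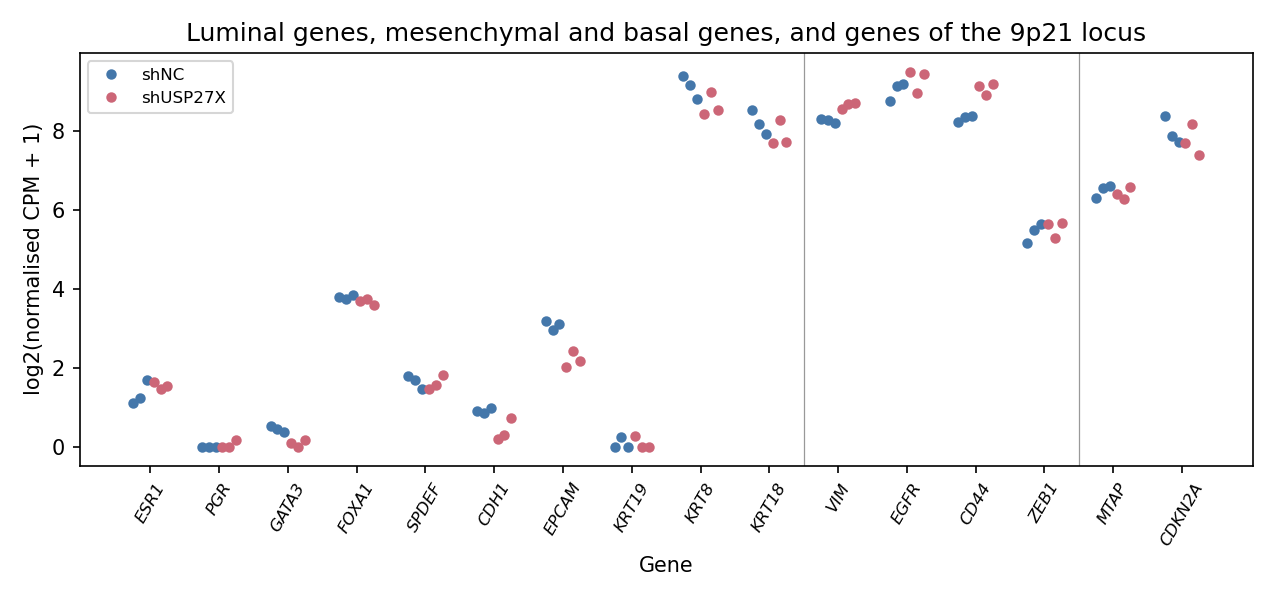
Levels of luminal genes (left), mesenchymal and basal genes (middle) and genes of the locus known to be lost in MCF7 (right) in each library, as log2(normalised CPM + 1); blue points are the 3 shNC libraries and red points the 3 libraries labelled shUSP27X. ESR1 stayed between 1.15 and 2.21 CPM, whereas MTAP stayed between 75.7 and 96.2 CPM.

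Between the groups, 2874 of the 15007 genes tested differed at an adjusted p under 0.05, 1566 higher and 1308 lower in the libraries labelled shUSP27X. With library size only as the scaling, 2954 passed, and the balance turned to 1429 higher and 1525 lower. Of the 2874, 403 were at least 2-fold higher and 268 at least 2-fold lower. Protein-coding genes made up 1443 of the higher and 1188 of the lower genes. Library profiles correlated at r = 0.982 to 0.992 within groups and 0.963 to 0.976 between them, and the first principal component, with 55.0% of the variance, separated the groups. The second (23.0%) set shNC 1 and shUSP27X 2 apart from the rest of their groups. Without these libraries, a choice made after seeing the data, 5764 genes passed (2872 higher, 2892 lower). The count also moved by over 1.5 times when a single library was left out: 1160 without shNC 2, 1336 without shUSP27X 1, 1482 without shUSP27X 3 and 4587 without shUSP27X 2.

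Among protein-coding genes at 4 CPM or more, the largest rises were in a heat-inducible chaperone gene and in genes of the extracellular matrix and cell surface. HSPA6 had 2 counts over the 3 control libraries and 535 over the others, a ratio of 276 (95% counting interval 76.0 to 2284). Both control counts were in shNC 2. Without it the control count was 0, and HSPA6 was at least 115-fold higher, taking 3 counts over the 2 remaining control libraries as the limit. HSPA6 has a close copy, HSPA7, so the assignment of its reads is uncertain. The collagenase gene MMP1 rose from 1.11 ± 0.734 to 51.2 ± 4.51 CPM (SD, n = 3 each; log2 fold change 5.46, SE 0.29, adjusted p = 3.6e-05). Of its 10, 32 and 9 control counts most were in shNC 2, and its log2 fold change was 6.19 without that library. ANTXR2, which encodes a cell-surface receptor for anthrax toxin, rose from 6.43 ± 1.10 to 91.4 ± 7.46 CPM (log2 fold change 3.83, SE 0.15). EDIL3 (3.04), LAMA4, a laminin chain gene (2.98), and CLEC2B (2.97) followed on the log2 scale. The largest falls were in ABCA13, a transporter gene (7.42 ± 0.439 to 0.751 ± 0.225 CPM; log2 fold change -3.29, SE 0.24), the Wnt ligand gene WNT10B (-2.89), the neuropeptide gene GAL (-2.83; 59.97 ± 11.2 to 8.46 ± 3.61 CPM), SLC12A3 (-2.63), ENOX1 (-2.26) and ADGRE2 (-2.15). All 12 genes had adjusted p values of 0.00041 or less.

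Genes of ribosome biogenesis fell as a list. Of 40 tested, 31 fell and none rose (35 and 0 adjusted over the list alone), with a median log2 fold change of -0.58 (camera adjusted p = 1.2e-18; adjusted p = 0.032 with an estimated correlation). They included NOLC1, a nucleolar phosphoprotein gene (391 ± 11.5 to 199 ± 3.62 CPM; -0.98), the nucleolar regulator gene LYAR (-1.27) and DKC1, the pseudouridine synthase gene (-0.998). Of 50 cytosolic ribosomal protein genes, 10 fell and none rose (17 and 0 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 2.6e-07; adjusted p = 0.49 with an estimated correlation). The median was -0.27 without shNC 1, and the list was not called by fry (adjusted p = 0.12; 1.8e-19 to 0.49 over all alternatives). Their share of all counts was 4.25% ± 0.635 (SD, n = 3) in shNC and 3.12% ± 0.591 (SD, n = 3) in the libraries labelled shUSP27X (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). That share was highest within each group in shNC 1 (4.98%) and shUSP27X 2 (3.80%). Across genes, which are not independent replicates, the log2 fold change correlated with GC content at a Spearman rho of -0.18 and with gene length at 0.16.

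Genes of the G1/S transition and DNA replication also fell. Of 42 tested, 17 fell and none rose (27 and 0 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 2.7e-09; adjusted p = 0.032 with an estimated correlation). Examples were E2F2, an activator of S-phase genes (54.9 ± 2.47 to 28.4 ± 1.99 CPM; -0.95), the phosphatase gene CDC25A (-0.76) and UHRF1 (-0.70). Among 45 G2/M and mitosis genes, 2 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.17), among them MYBL2 (-0.83). Of 16 replication-dependent histone genes tested, 3 fell and none rose, the same counts adjusted over the list alone (median -0.32; camera adjusted p = 0.028; adjusted p = 0.43 with an estimated correlation), with HIST1H2BJ at -1.11. The histone call was also lost without shNC 1 (adjusted p = 0.058), shUSP27X 1 (0.081) or shUSP27X 3 (0.090), and without both shNC 1 and shUSP27X 2 (0.053), with a range of 0.0064 to 0.43 over all alternatives, and the median was -0.50 without shUSP27X 2. Of 27 p53 targets, 5 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.12). The cyclin-dependent kinase inhibitor gene CDKN1A rose from 28.5 ± 2.30 to 129 ± 14.95 CPM (2.18, SE 0.12), TP53INP1 rose (2.26) and PLK3 rose (0.83).

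Immediate early genes, which respond rapidly to growth factor and stress signals, were higher. Of 29 tested, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 7.7e-14; adjusted p = 0.061 with an estimated correlation). FOS rose from 8.70 ± 1.11 to 51.1 ± 5.24 CPM (2.55, SE 0.14), EGR1 by 1.78 and the phosphatase gene DUSP4 by 1.599 on the log2 scale. In the NF-kB inflammatory list, 10 of 27 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.21; camera adjusted p = 0.0010; adjusted p = 0.10 with an estimated correlation). The median of this list was 0.32 without shNC 3 and 0.35 without shUSP27X 2. The cytokine genes CXCL8 (2.96), IL1B (2.54) and IL1A (1.28) rose. The 3 that fell were chosen after their values were seen: CCL2, a chemokine gene (1.21 ± 0.328 to 0.206 ± 0.170 CPM; -2.46, adjusted p = 0.015), and NFKB1 (-0.44, 0.013) and NFKB2 (-0.49, 0.030), which encode NF-kB subunits. Their calls were lost without shUSP27X 1, and those of NFKB1 and NFKB2 also without shNC 2. For CCL2, NFKB1 and NFKB2 the adjusted p values reached 0.060, 0.075 and 0.13 over all alternatives. NFKB2 was lost without shNC 1 or shUSP27X 3 too. The log2 fold change of CCL2 ran from -3.34 to -2.06 when single libraries were left out, and CCL2 was tested in 14 of the 15 alternatives. Its mean in the libraries labelled shUSP27X, 0.206 CPM, lay near the level of 3 counts there (0.198 to 0.226 CPM). The size of its fall is therefore uncertain. Of 16 heat shock genes, 6 rose and none fell (7 and 2 adjusted over the list alone; median 0.20; camera adjusted p = 0.020; adjusted p = 0.34 with an estimated correlation). The heat shock call was also lost without shUSP27X 2 (adjusted p = 0.069) and with limma-voom (0.069), with a range of 0.00099 to 0.34 over all alternatives. HSPA8 rose from 335 ± 16.2 to 684 ± 13.8 CPM (1.03) and HSPH1 by 0.75; HSPA1A rose by 1.46 but shares near-identical sequence with HSPA1B.

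Mesenchymal and fibroblast markers were higher as a list. Of 20 tested of 30, 9 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 3.2e-07; adjusted p = 0.032 with an estimated correlation). Fibronectin, FN1, rose to 145 ± 20.5 CPM (SD, n = 3; log2 fold change 2.60, SE 0.16), SERPINE1 by 1.63 and TGFBI by 1.46. With no filter on low counts the median of this list was -0.02, while the camera test still pointed upward (adjusted p = 4.0e-07; 5.2e-08 to 0.032 over all alternatives). Of 15 basal epithelial markers, 5 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.13). CD44 (0.75) and LAMA3 (0.86) rose and FOXC1 fell (-0.58). Of 13 luminal genes tested of 24, 2 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.66): MLPH (1.89) and MUC1 (0.58) rose and EPCAM fell (-1.04). SNAI1, which encodes the transcription factor SNAIL, had a log2 fold change of -0.37 (adjusted p = 0.54), and ESR1 one of 0.30 (adjusted p = 0.52). When single libraries were left out, SNAI1 ran from -0.71 to -0.02 and ESR1 from 0.13 to 0.62, and neither passed in any alternative.

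Cholesterol synthesis genes were higher. Of 25 tested, 9 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 7.0e-06; adjusted p = 0.061 with an estimated correlation). INSIG1 rose from 101 ± 4.16 to 208 ± 3.34 CPM (1.05), the low-density lipoprotein receptor gene LDLR by 0.94 and MSMO1 by 1.15. Of 15 mitochondrially encoded genes, 3 rose and none fell, the same counts adjusted over the list alone (median 0.28; camera adjusted p = 0.023; adjusted p = 0.49 with an estimated correlation), including MT-ATP8 (0.72) and MT-ND6 (0.87). MT-ND6 lies on the opposite strand to most other mitochondrial genes, and the strand setting of the counting is not given in the sources used here. The mitochondrial list call was also lost without shNC 1 (adjusted p = 0.058) or shUSP27X 3 (0.11; median 0.17) and by fry (0.078), with a range of 1.9e-05 to 0.49 over all alternatives. The mitochondrial share of counts was 6.57% ± 0.334 in shNC and 7.69% ± 0.985 in the libraries labelled shUSP27X (SD, n = 3 each; two-sided exact permutation p = 0.3).

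**Figure D3:**
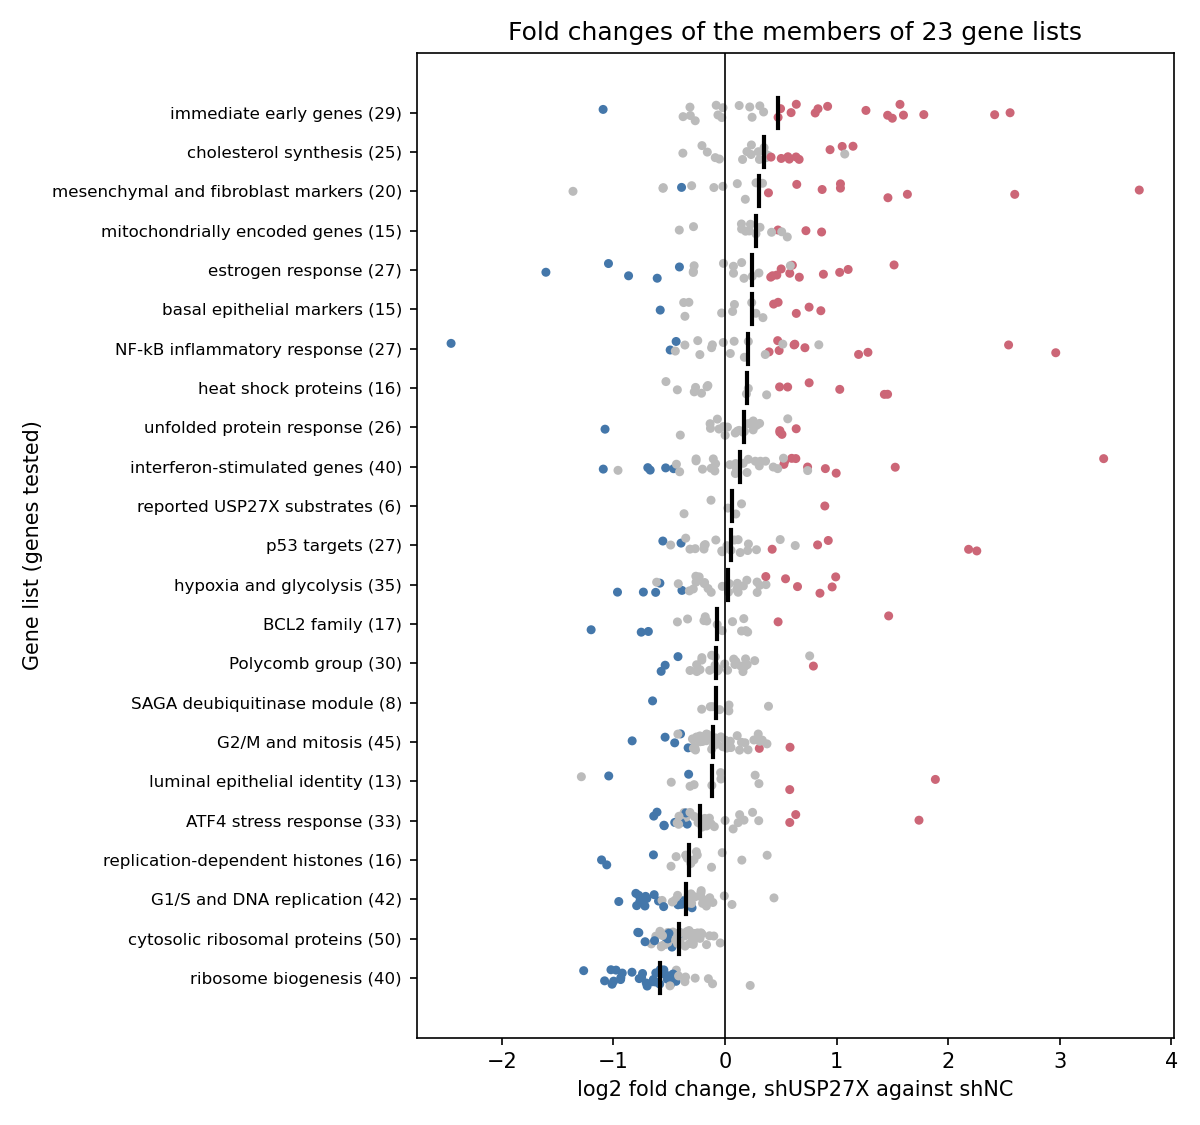
Log2 fold changes (horizontal axis) of the tested members of each of the 23 gene lists, with the number tested in brackets; red and blue points passed an adjusted p of 0.05 upward and downward, grey points did not, and black bars are list medians. Ribosome biogenesis had the lowest median (-0.58) and immediate early genes the highest (0.48).

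The remaining lists were not called by camera with the preset correlation. Among 6 reported USP27X substrates, 1 rose and none fell, the same counts adjusted over the list alone (camera adjusted p = 0.45): DDX58, which encodes the RNA sensor RIG-I (16.8 ± 0.572 to 31.3 ± 2.80 CPM; 0.89). Of the other substrate genes, BCL2L11 had a log2 fold change of 0.15 (adjusted p = 0.54), CCNE1 of 0.10 (0.71) and HES1 of -0.13 (0.64), none past the threshold in any alternative. When single libraries were left out, BCL2L11 ran from 0.014 to 0.25, HES1 from -0.31 to -0.0061 and CCNE1 from -0.026 to 0.25. The libraries measured mRNA only, so the values of this list do not test the level of any substrate protein. Of 30 Polycomb group genes, 1 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.45). The methyltransferase gene EZH2 fell by 0.57 and PHF1 rose by 0.79 on the log2 scale. Of 8 genes of the SAGA deubiquitinase module, 1 fell and none rose, the same counts adjusted over the list alone (camera adjusted p = 0.51). Of 17 BCL2 family genes, 2 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.55), with BIK at -1.20 and BMF at 1.47. Among 33 ATF4 stress response genes, 3 rose and 8 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.056). GDF15 (1.74) and STC2 (0.58) rose and PSPH, of serine synthesis, fell (-0.61). The ATF4 list passed without shNC 3 (adjusted p = 0.039), without shUSP27X 2 (0.024) and without both shNC 1 and shUSP27X 2 (0.039), with a range of 0.014 to 0.49 over all alternatives. Of 27 estrogen response genes tested of 36, 11 rose and 5 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.081). TPBG (1.51) and CA12 (0.88) rose and ABCA3 fell (-1.04). Of the 36, 20 were at 20 CPM or more in all 6 libraries and 6 under 1 CPM in all. GREB1, TFF1 and PGR, chosen after their values were seen, reached at most 1.06, 1.44 and 0.132 CPM. Of 26 unfolded protein response genes, 4 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.12), with DNAJB9 at 0.64. Of 40 interferon-stimulated genes, 9 rose and 5 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.12), with STAT2 (0.996), B2M (0.54) and OAS2 (1.53) higher. Of 35 hypoxia and glycolysis genes, 6 rose and 5 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.81), with HK2 at -0.96, BHLHE40 at 0.65 and P4HA2 at 0.85. The hypoxia median was 0.03 and its mean 0.004, while the camera test pointed downward.

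Other settings called some of the lists that camera with the preset correlation did not. The fry test asks whether a list's genes move, on balance, one way, without comparing them with other genes. It called p53 targets (adjusted p = 0.0028; 0.0028 to 0.34 over all alternatives), basal markers (0.0041; to 0.37), the unfolded protein response (0.0075; to 0.42) and estrogen response genes (0.015; to 0.42). It also called the SAGA module (0.023; to 0.60), USP27X substrates (0.034; to 0.55), G2/M and mitosis genes (0.034; to 0.44) and interferon-stimulated genes (0.039; 0.031 to 0.42 over all alternatives). With no filter on low counts, camera called the ATF4 stress response (adjusted p = 0.014), p53 targets (0.014), interferon-stimulated genes (0.031), the unfolded protein response (0.031) and estrogen response genes (0.047). With limma-voom it called the ATF4 stress response (0.020) and the unfolded protein response (0.040), and with library size only the ATF4 stress response (0.048).

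Some of the named genes passed the test with all 6 libraries but not without a particular one. CBX2, a Polycomb subunit gene, fell from 37.2 ± 2.38 to 25.7 ± 2.90 CPM (SD, n = 3 each; log2 fold change -0.54, SE 0.12, adjusted p = 0.017). Its adjusted p was 0.090 without shNC 2, 0.079 without shUSP27X 1 and 0.076 without shUSP27X 3, with a range of 0.00012 to 0.090 over all alternatives. ATXN7L2, of the SAGA list (-0.65), was past the threshold in the leave-outs only without shUSP27X 2, with adjusted p values of 0.079, 0.090, 0.057, 0.11 and 0.11 without shNC 1, shNC 2, shNC 3, shUSP27X 1 and shUSP27X 3. Among the ribosomal protein genes, RPL7 (-0.51) was lost without shNC 2 (0.052), shUSP27X 1 (0.072) or shUSP27X 3 (0.064), and RPL12 (-0.78) without shUSP27X 1 (0.070) or shUSP27X 3 (0.065). RPL5 (-0.40) was lost without shNC 1 (0.055), shNC 2 (0.083), shUSP27X 1 (0.10) or shUSP27X 3 (0.070). The mitotic genes TPX2 (-0.45) and CDC20 (-0.54) were lost without shNC 2 (0.060 and 0.065) or shUSP27X 1 (0.057 and 0.069), and CDC20 also without shUSP27X 3 (0.064). MCL1 (0.48) was lost without shNC 2 (0.065), shUSP27X 1 (0.051) or shUSP27X 3 (0.050), and MT-CO2 (0.47) without shNC 2 (0.079) or shUSP27X 3 (0.055). HIST2H2BE (-0.64) was lost without shNC 2 (0.052) or shUSP27X 1 (0.050), and HIST1H2BG (-1.06) without shNC 2 (0.087), shNC 3 (0.086), shUSP27X 1 (0.066) or shUSP27X 3 (0.098). DERL3 (-1.08) and EDEM1 (0.49), of the unfolded protein response list, were lost without shNC 1 (0.070 and 0.077), shNC 2 (0.080 and 0.11), shUSP27X 1 (0.096 and 0.10) or shUSP27X 3 (0.092 and 0.11).

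Members that complete list counts of 5 or fewer lay outside the rule for named genes and were chosen after their values were seen. Of the immediate early genes DUSP2 fell (log2 fold change -1.09), and of the mesenchymal markers COL5A1 (-0.39). Among p53 targets CCNG1 (0.42) and ZMAT3 (0.93) rose and DDB2 (-0.56) and AEN (-0.39) fell. Among G2/M and mitosis genes BUB3 (0.31) and CENPE (0.58) rose and FOXM1 (-0.40) and MAD2L1 (-0.33) fell. ANXA1 (0.44), ITGB4 (0.48) and ITGA6 (0.64) rose among basal markers, and TFAP2A (-0.33) fell among luminal genes. SLC7A11 (0.63) rose in the ATF4 list, and DNAJC3 (0.51) and ERN1 (0.49) in that of the unfolded protein response. KDM2B (-0.42), of the Polycomb group, and BOK (-0.75) and HRK (-0.69), of the BCL2 family, fell. Among estrogen response genes MYC (-0.86), KCNK5 (-1.61), FKBP4 (-0.61) and SIAH2 (-0.41) fell. Among interferon-stimulated genes PSMB9 (-1.09), IFITM3 (-0.69), USP18 (-0.67), IFITM2 (-0.53) and TAP1 (-0.46) fell; IFITM2 and IFITM3 are close copies, so the assignment of their reads is uncertain. Among hypoxia and glycolysis genes SLC2A3 (-0.73), PDK1 (-0.62), MXI1 (-0.58) and GPI (-0.39) fell. With CCL2, NFKB1 and NFKB2 these were 36 genes, and only MYC, KCNK5, PDK1, DUSP2 and PSMB9 kept the call in all alternatives. The call was lost by 28 genes without shUSP27X 1, 27 without shNC 2, 23 without shUSP27X 3, 19 without shNC 1 and 10 without shNC 3. None changed direction, and the highest adjusted p was 0.17 (BUB3).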

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

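The setting that left out shNC 1 and shUSP27X 2 was chosen after seeing the data; the others were planned. USP27X stayed between -0.19 and -0.01 on the log2 scale and passed in none of the 15 alternatives. Of the 77 named genes past the threshold, 64 kept direction and call in all alternatives, and of the 10 called lists 2 did (ribosome biogenesis, G1/S and DNA replication). The replicate numbers did not pair the samples (r of deviations -0.29, -0.15 and 0.31 for the numbers 1, 2 and 3). With the replicate block, 2120 genes passed, of which 2072 were among the 2874, USP27X was at -0.09, and the paired calls of RPL5 (adjusted p = 0.064), HIST1H2BG (0.057) and 16 of 36 genes named outside the rule were lost. Leaving out 1 library gave 1160 to 4587 genes, 700 to 2281 higher and 460 to 2306 lower, and 190 to 424 at least 2-fold lower. Leaving out shNC 1 and shUSP27X 2 together gave 5764 genes, 2872 higher and 2892 lower. An estimated correlation gave 3 lists and fry 16, which asks a different question. Some directions reversed. Over the leave-outs, CCNE1 ran from -0.026 (without shUSP27X 2) to 0.248, and the list medians from -0.137 to 0.014 (without shNC 1) for the BCL2 family, -0.103 to 0.0037 (without shUSP27X 2) for SAGA, -0.024 (without shUSP27X 2) to 0.094 for USP27X substrates and -0.022 (without shUSP27X 2) to 0.062 for hypoxia and glycolysis, which was also below 0 without shNC 3 or shUSP27X 3. With shNC 1 and shUSP27X 2 left out, SAGA was at 0.032, hypoxia at -0.0052 and the substrates at -0.0040. With no filter, hypoxia was at -3.01e-06 and mesenchymal markers, at 0.31 with the filter, at -0.021. The cause was not tested. Depth limits USP27X, at 81 to 105 counts per library: its interval leaves changes of -0.46 to 0.28 open.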

Other observations

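The tests chosen only after the result was seen were those of the gene families and of MYC, the interval of USP27X, the exchange of libraries, both tests on the luminal median and the leaving out of shNC 1 and shUSP27X 2. The families were grouped by symbol or by the transcription factor families of the deposited table, and those described are a selection made after the values were seen. The RPL, RPS, MRPS, CD, HSPA and POLR symbol families also had camera adjusted p values under 0.05. With an estimated correlation, the lowest camera adjusted p was 0.26 over the symbol families and 0.27 over the transcription factor families. Among 29 interleukin and interleukin receptor genes tested, 14 rose and 5 fell in the libraries labelled shUSP27X (camera adjusted p = 0.00037 over 86 symbol families; adjusted p = 0.26 with an estimated correlation). IL1RL1 (log2 fold change 3.21), IL13RA2 (2.10), IL1R1 (1.88) and IL18R1 (1.85) rose, and IL15RA (-1.44) and IL32 (-1.21) fell. Of 15 semaphorin genes, 6 rose and 1 fell (camera adjusted p = 0.0017; adjusted p = 0.26 with an estimated correlation), with SEMA3A at 1.93. Of 16 tetraspanin genes, 6 rose and 1 fell (camera adjusted p = 0.00037; adjusted p = 0.26 with an estimated correlation), with TSPAN5 at 1.66 and TSPAN8 at 1.41.

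Of 15 TIMM genes, of mitochondrial import, 7 fell and none rose (camera adjusted p = 0.0021; adjusted p = 0.55 with an estimated correlation), and of 49 MRPL genes, of the mitochondrial ribosome, 7 fell and none rose (camera adjusted p = 0.00037; adjusted p = 0.72 with an estimated correlation). Of 81 homeobox genes, 2 rose and 11 fell (camera adjusted p = 0.013 over 15 transcription factor families; adjusted p = 0.46 with an estimated correlation), with TGIF2 at -1.86 and SIX2 at -1.18. Of 39 bZIP genes, 8 rose and 1 fell (camera adjusted p = 0.013; adjusted p = 0.27 with an estimated correlation), among them FOSB (2.42), MAFB (2.27) and JUN (1.57). The 8 also included FOS (2.55), of the immediate early list, so the bZIP call is not separate from the call of that list. The 14 family members named here beside FOS were chosen after their values were seen, and all kept direction and call in the 15 alternatives. MYC, of the estrogen response list, fell from 595 ± 49.1 to 327 ± 43.4 CPM (SD, n = 3 each; log2 fold change -0.86, adjusted p = 0.0021).

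USP27X mRNA was not lower in the libraries labelled shUSP27X. Too few counts cannot account for this if the hairpin acted 2-fold on mRNA, since the lower bound of the 95% interval was -0.46. Of 2569 windows of 50 bases, 0% occurred in transcripts of other genes, which argues against reads shared with annotated transcripts in the same direction. The search did not cover the opposite strand or sequence outside annotated transcripts, so reads from there stay open. An exchange of a control library and one labelled shUSP27X is argued against by 0 of 6 libraries correlating better with the other group. A hairpin that lowered the protein but not the mRNA, a hairpin without effect on USP27X, or a difference between the cultures that has nothing to do with USP27X may each remain, and none was tested.

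Several luminal genes, though not KRT8, KRT18, TFAP2A or MUC1, were low in libraries labelled MCF7. The luminal median, 1.36 CPM in the highest library, was under the limit set for a small share of other cells beside MCF7. That limit was set after the values were seen, and the median restates the pattern, so the limit by itself cannot decide on this explanation. A small share of other cells would, however, leave most of the RNA from MCF7. Of the 24 luminal genes, 12 stayed under 1 CPM in all 6 libraries, and 4 were at 20 CPM or more in all. For those 12 genes, this argues against a small share, as far as MCF7 expresses them. The control libraries were low too, at 1.36 CPM in the highest, which argues against loss through the hairpin against USP27X. The lowest MTAP level, 75.7 CPM, met what was written before it was seen for cells other than MCF7. All 3 genes of that locus, MTAP, CDKN2A and CDKN2B, were at 20 CPM or more in all 6 libraries. These values argue against libraries made of MCF7 cells alone and go with cells other than MCF7. This rests on background knowledge of the locus, and which other cells were present was not tested.

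Ribosome biogenesis genes were lower in the libraries labelled shUSP27X. Gene length or GC bias is argued against by a median of -0.60 after the trend was removed (-0.58 before). Without shNC 1 and shUSP27X 2 the median was -0.61, so the fall did not rest on these libraries. They belong to opposite groups and lie on the same side of the second principal component. A drift they share would move both groups the same way, so this test could hardly have favoured it. The hairpin named by the labels stays open, as does a difference in culture or handling between the groups, and neither was tested.

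Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 2874 genes past the edgeR threshold and 671 at least 2-fold. The highest other gave 0 and 0, with at most 2984 genes at an unadjusted p under 0.05 (5022 in the real split). That split joined shNC 1, shNC 2 and shUSP27X 2. For gene lists, 1 split, the real one, called 10, and the highest other called 8, so a list called with the preset correlation is weak evidence by itself. With 10 splits the share cannot go under 0.05. Every other split had libraries of both groups on each side, so the difference between the groups added to its spread and lowered its gene calls. Part of that difference also stayed in its contrast, so its list calls need not all be false. The other splits therefore do not show what grouping at random would give without a group difference.

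A copy number or clone difference between the groups was tested on the medians of whole chromosomes. The largest distance of a nuclear chromosome's median log2 fold change from the median of all genes was 0.110 (chromosome 22, 360 genes), under the 0.3 set beforehand. The mitochondrial genome, which does not bear on nuclear copy number and was left out after its value was seen, was at 0.156 (25 genes). This argues against gain or loss of a whole chromosome, and smaller segments, or clones that do not differ by whole chromosomes, stay open.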
